A study of Rattus norvegicus with 18 samples.

How the data were processed

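Total RNA from the nucleus accumbens of 18 male Sprague-Dawley rats was extracted with Qiagen chemistry, and biotin-labelled cDNA was made from 100 ng per array with the Affymetrix WT Plus kit, per the labels' protocols. The 6 rats of each of 3 groups were selected on RNA quality and integrity, per the design text of the series. Values were made with Affymetrix Expression Console, per the submitters' processing notes. The deposited values were taken as log2 because of their range. Array medians lay close together, as after a normalization between arrays. Whether and how the authors normalized, the summarisation method, its version and any filter are not given in the sources used here. Raw intensity files were not analysed here.

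The table held 70580 features with 0 missing values, of which 1738 were control features. Gene symbols came from the platform annotation and were updated through gene numbers against the RefSeq annotation of the rat assembly GRCr8, used for names alone. Of the 68842 other features, 23446 carried 1 gene symbol, 505 several and 44891 none, and 22077 were matched by gene number. Features with several symbols or none were left out of gene tests. For the 1182 genes with more than 1 feature the feature with the highest mean over all arrays was kept, which left 22093 genes. No filter on low values was applied. The 1153 negative control features had a median of 6.37, and 10520 genes lay below it. Precision is limited by the 6 arrays per group, since arrays give no read depth.

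Groups were taken from the labels. One limma fit (version 3.58.1, R 4.3.3, default empirical Bayes settings, group as the only term, no block) used all 18 arrays, so that the 3 groups shared 1 estimate of the spread per gene. Contrasts were shock resistant against control, shock sensitive against control, shock resistant against shock sensitive, and the mean of both methamphetamine groups against control, and a moderated F test covered any difference among the 3 groups. P-values were adjusted by the Benjamini-Hochberg method over all genes with a threshold of 0.05. The nominal criterion was an unadjusted p under 0.05 with at least a 1.3-fold difference. Pdyn and Penk were also compared by two-sided exact permutation tests of group means, adjusted over 6 tests. Correlations across arrays used 100000 permutations over 18 arrays and exact permutation within groups of 6.

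The 35 gene lists, among them markers of the other cell types a dissection could hold, held 718 distinct genes, of which 669 were measured. Each list was tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. Fry's directional p asks whether a set moves on balance one way and its mixed p whether members change in either direction, and neither compares the set with other genes. The groups, comparisons, tests, thresholds, gene lists and the rule for named genes were fixed before the data were examined. The rule named, for each comparison of 2 groups, the opioid list, the 10 higher and the 10 lower genes with the smallest limma p among symbols that are not provisional identifiers and at least 1.2-fold, and the 2 to 4 members with the smallest p of each list that camera called or that had a member past the threshold over the list alone. For the F test it named those among the 10 smallest p.

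Alternatives were quantile normalization, centring of each array on its median, all features of the array, the mean of a gene's features, genes at or above the median level alone, trend and robust variance estimation, array quality weights, the first principal component of the residuals as a covariate, 2 groups alone in the fit, fold thresholds of 1.2 and 1.5, a block by replicate number, controls split between the comparisons, and each array left out in turn. Chosen after seeing the data were the medium spiny neuron marker mean as a covariate and a fit without control replicate 1 and shock-sensitive replicate 4. The model, the calls and the set test were tested on simulated data made for shock-resistant rats against controls. With 100 genes changed by 0.5 and 100 by 1 on the log2 scale it made 17 false calls, and 0 calls in a comparison left unchanged. A microglia list raised by 0.3 was called and 0 other lists were. The simulated genes were drawn independently, so false list calls from genes that vary together were not tested. Counts were set beside 100 random splits of the arrays. Correlation and overlap of comparisons that share controls were set beside 100 simulations of unchanged groups each. Permutation tests and figures were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.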

Results

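Gene expression was measured in the nucleus accumbens, the ventral part of the striatum, of 18 male Sprague-Dawley rats, with 1 whole-transcript array per rat. The arrays profile methamphetamine self-administration in which footshock was the adverse consequence, and they fall into 3 groups of 6 rats named control, shock resistant and shock sensitive. In such experiments shock-resistant rats keep taking the drug despite the shock and shock-sensitive rats reduce their intake. What the control rats received is not given in the sources used here. Array medians over all features lay between 5.39 and 5.53 on the log2 scale. Pairs of arrays correlated at 0.993 to 0.998 across features, which are not independent replicates. The number of arrays limits the precision of every comparison. Of 22093 genes tested, 47.6% had a mean below 6.37, the median of 1153 negative control features. Of the genes named in this text, those below it were Ahsp, C1h16orf92, Cort, Cxcl10, Defb49, Fosl1, Gcnt4, Gdf9, Insl5, Irs4, LOC102554555, Mir29a, Mir3559, Nmu, Npbwr1l1, Nrtn, Olr1088, Oog1, Or2g7, Or6c33, Pomc, RT1-Da, Slurp1, Sostdc1, St6gal1l, Taar4, Tmem30b, Vom1r81 and Vom2r78.

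Medium spiny neurons, the projection neurons that make up most of the striatum, left an uneven signal on the arrays. The mean log2 value of an 18-gene marker list was 12.47 ± 0.60 in controls, 12.78 ± 0.25 in shock-resistant rats and 12.27 ± 0.57 in shock-sensitive rats (SD, n = 6 each). It was lowest in shock-sensitive replicate 4, at 11.28, and in control replicate 1, at 11.3. The first principal component held 24.2% of the variance and correlated with this mean at Pearson r = −0.93 and Spearman rho = −0.84 over the 18 arrays (permutation p = 1e-05, the smallest 100000 permutations can give, and 4e-05). Adjusted over 9 relations with the marker mean these were 9e-05 and 0.00036, and r was −0.80 without the 2 farthest arrays. Slc17a7, the vesicular glutamate transporter of cortical neurons, ranged from 6.34 to 10.54 among arrays. Ttr, the transport protein secreted by the choroid plexus, read 16.58 in shock-resistant replicate 4 and 5.67 to 8.52 elsewhere. Both genes were chosen after the values were seen.

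Proenkephalin and prodynorphin, the opioid peptide precursors named in the title of the series, were compared among the groups first. Pdyn averaged 13.07 ± 0.78 in shock-resistant rats, 11.97 ± 0.53 in shock-sensitive rats and 11.94 ± 0.91 in controls (log2, SD, n = 6 each). Its mean in shock-resistant rats was 2.18-fold that of controls and 2.14-fold that of shock-sensitive rats. Penk averaged 15.59 ± 0.37, 14.94 ± 0.39 and 15.16 ± 0.48 in the same order, so that shock-resistant rats stood 1.57-fold above shock-sensitive rats and 1.35-fold above controls. In shock-sensitive rats against controls the log2 differences were 0.026 for Pdyn and −0.21 for Penk.

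Exact two-sided permutation tests over 924 orderings gave p = 0.0238 for Pdyn and p = 0.0216 for Penk between the methamphetamine groups, both 0.0714 after Benjamini-Hochberg adjustment over 6 tests. For Pdyn against controls in shock-resistant rats the exact p was 0.0476, adjusted to 0.0952, and for Penk 0.117, adjusted to 0.175. In shock-sensitive rats against controls the exact p was 0.955 for Pdyn and 0.403 for Penk, adjusted to 0.955 and 0.483. The smallest p this design allows is 0.00216. None of the 6 comparisons passed after adjustment. Pdyn lay above the shock-sensitive median in 5 of 6 shock-resistant arrays and above every shock-sensitive array in 4, and Penk in 6 and 3. Against controls, 6 of 6 shock-resistant arrays exceeded the control median of Pdyn and 3 exceeded its highest array. Over all genes the limma adjusted p of Pdyn was 0.335 for shock-resistant rats against controls (log2 difference 1.13 ± 0.40, SE) and 0.753 for the 2 methamphetamine groups, and that of Penk was 0.463 and 0.753.

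**Figure D1:**
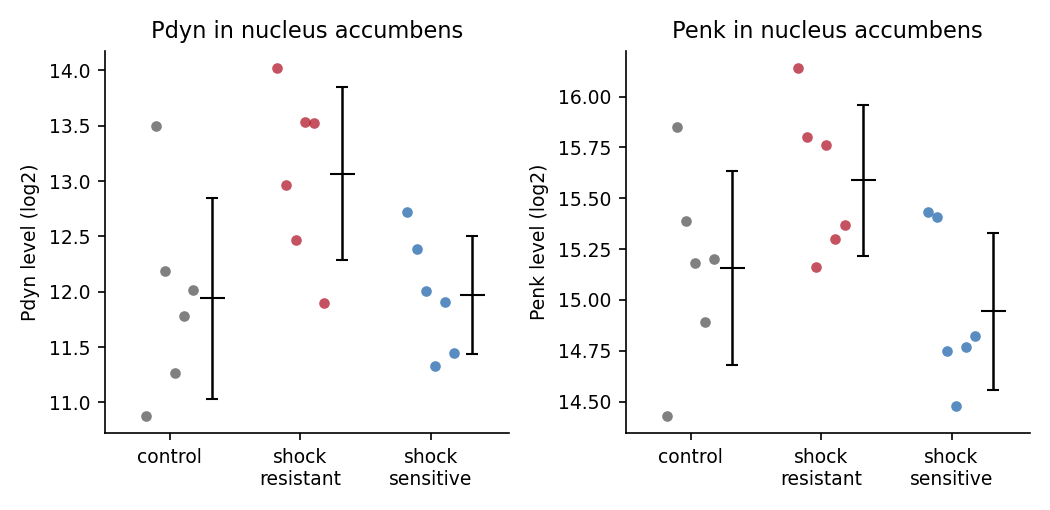
Log2 values of Pdyn and Penk (vertical axes) in the 6 arrays of each group (horizontal axis), 1 point per array with the group mean and SD as a line with bars. Pdyn ran from 11.9 to 14.02 in shock-resistant rats and from 11.33 to 12.72 in shock-sensitive rats, and control replicate 2 had the highest control value, 13.5.

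The opioid receptors and other peptide precursors gave smaller differences. Oprk1, the kappa receptor for dynorphin, was 0.27 higher in shock-resistant rats than in controls on the log2 scale and 0.26 higher than in shock-sensitive rats, while shock-sensitive rats differed from controls by 0.005, or −0.004 after median centring. Oprl1, the nociceptin receptor, differed by −0.21, 0.13 and −0.34 in shock-resistant against control, shock-sensitive against control and shock-resistant against shock-sensitive rats. In the same order Oprm1, the mu receptor, differed by −0.098, −0.007 and −0.091, and Oprd1, the delta receptor, by 0.08, −0.062 and 0.14. Only 1 of 6 shock-resistant arrays lay above the control median of Oprd1, and its 0.08 fell as low as −0.12 with 1 array left out. Pnoc, the nociceptin precursor, differed by −0.053, 0.098 and −0.15, and Pomc, the precursor of beta-endorphin, by 0.17, 0.037 (−0.011 after quantile normalization) and 0.14. In the 8-gene opioid list 0 genes passed in any comparison, adjusted over all genes or adjusted over the list alone. The camera set test gave the list an adjusted p of 0.43, 0.775 and 0.138.

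Pdyn and Penk varied with the marker mean of medium spiny neurons, the cells that make both peptides. Over all 18 arrays Pearson r was 0.67 for Pdyn and 0.82 for Penk (permutation p = 0.002 and 2e-05, adjusted over 9 relations to 0.0061 and 9e-05). Spearman rho was 0.63 and 0.82 (permutation p = 0.0067 and 0.00012, adjusted to 0.02 and 0.00054), and r without the 2 farthest arrays was 0.55 and 0.76. Within controls, shock-resistant and shock-sensitive rats Pearson r was 0.58, 0.54 and 0.87 for Pdyn (exact permutation p = 0.24, 0.26 and 0.017, adjusted to 0.26, 0.26 and 0.025). For Penk it was 0.73, 0.88 and 0.88 in the same order (exact permutation p = 0.12, 0.0097 and 0.0097, adjusted to 0.16, 0.017 and 0.017). Without the 2 farthest arrays these were 0.18, −0.33 and 0.75 for Pdyn and −0.12, 0.53 and 0.84 for Penk. Those within controls, and that of Pdyn within shock-resistant rats, thus rested on 2 arrays. By Spearman rho, Penk within shock-sensitive rats did not pass (0.83, exact permutation p = 0.058, adjusted to 0.088). Penk within shock-resistant and Pdyn within shock-sensitive rats did (0.94 each, exact permutation p = 0.017, adjusted to 0.03).

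**Figure D2:**
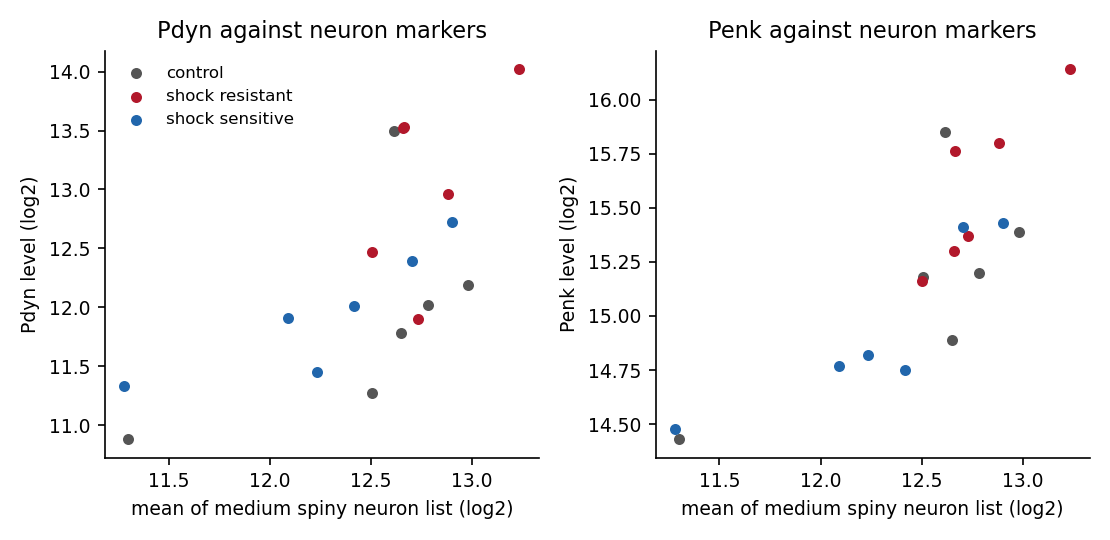
Log2 value of Pdyn and of Penk (vertical axes) against the mean log2 value of the medium spiny neuron marker list (horizontal axis), 1 point per array coloured by group. Control replicate 1 and shock-sensitive replicate 4 lie at the left, at marker means of 11.3 and 11.28, and r over the 18 arrays was 0.67 for Pdyn and 0.82 for Penk.

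The comparison of shock-resistant rats with controls asks what differs in rats that kept taking methamphetamine despite the shock. Bmal1, an activator at the core of the circadian clock, rose 1.44-fold, from 9.49 ± 0.19 to 10.01 ± 0.14 (SD, n = 6 each; log2 difference 0.53 ± 0.085, SE, limma adjusted p = 0.0467), and lay above every control in 6 of 6 arrays. Defb49, a beta-defensin gene, rose 1.62-fold, from 5.38 ± 0.24 to 6.07 ± 0.14, both below the negative control median (adjusted p = 0.0388, 6 of 6 arrays above every control). C1h16orf92 and LOC102554555, both below that median and chosen after the values were seen, completed the 4 genes past the threshold. They rose by 0.285 ± 0.04 and 0.36 ± 0.051 (adjusted p = 0.0151 each), with 6 of 6 arrays above every control. Far2, a fatty acyl-CoA reductase gene, stood 1.63-fold above controls (0.70 ± 0.13, adjusted p = 0.0897, 6 of 6 above every control). Reln, the gene of the secreted glycoprotein reelin, stood 1.85-fold higher (0.88 ± 0.20, adjusted p = 0.239, 3 of 6). Scgb1b24, a secretoglobin gene, stood 1.46-fold higher and Ptprn, a dense-core vesicle protein, 1.36-fold (adjusted p = 0.0897 and 0.184). Lower values were read for Mthfd1l, a mitochondrial folate enzyme (−0.30 ± 0.052, adjusted p = 0.0763), and Tp53bp2, which encodes a p53-binding protein (−0.41 ± 0.084, adjusted p = 0.181), in 6 of 6 arrays below every control. The pseudogenes Cdc34-ps1 and Tra2b-ps1 differed by −0.60 and −0.40. The other genes named by the same rule did not pass either. They were Oog1 (0.32, adjusted p = 0.0524), Gdf9, Slurp1 and Vom2r78, all below the negative control median, and, on the lower side, Rnf168, Gcnt4, Pex11a, Ppfia2 and Ptcd2 (−0.57 to −0.28).

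Over all genes 4 passed limma's adjusted threshold, all higher, while 2523 had an unadjusted p under 0.05 (1595 higher and 928 lower, against 1105 by chance). The nominal criterion, an unadjusted p under 0.05 and at least a 1.3-fold difference, took 175 genes, 81 higher and 94 lower. Quantile normalization gave 998 higher and 1025 lower at an unadjusted p under 0.05. The self-test of this comparison, on simulated data over 22093 genes, recovered 77% of 100 genes changed by 0.5 and 96% of those changed by 1 on the log2 scale. Its genes were drawn independently and many were changed at once. The adjusted threshold then lies at a larger unadjusted p than with the 4 genes called here. These shares therefore do not tell how many real changes of such sizes would be found. Bmal1 was past the threshold under 7 of 12 alternatives (adjusted p = 0.00537 to 0.185) and Defb49, C1h16orf92 and LOC102554555 under 8 of 11 each (0.0133 to 0.107, 0.0101 to 0.0992 and 0.0101 to 0.0992). These passes include the first residual principal component as a covariate, whose p-values may be too small. They also include the mean of a gene's features, which left the differences of these 4 genes as they were. Neither adds independent support. Genes passing numbered 0 over all features, with genes at or above the median level or with the 2 groups alone, 9 with array weights and 25 with the first residual principal component as a covariate. The count was 0 without shock-resistant replicate 1, 7 without control replicate 2, 1 without control replicate 4 or shock-resistant replicate 5, and 2 without control replicate 3 or shock-sensitive replicate 1, 3, 5 or 6. The nominal count was 105 without shock-resistant replicate 1. Bmal1 kept its call without control replicate 2, shock-resistant replicate 6 or shock-sensitive replicate 4 (adjusted p = 0.0194, 0.0498 and 0.0295). It lost the call without control replicates 1, 3, 4, 5 or 6 (0.0852, 0.0705, 0.13, 0.0808 and 0.0934), shock-resistant replicates 1 to 5 (0.163, 0.0825, 0.0702, 0.0624 and 0.0804) or shock-sensitive replicates 1, 2, 3, 5 or 6 (0.0558, 0.0595, 0.055, 0.0736 and 0.0863). Defb49 lost it without control replicates 3, 4 or 5 (0.0705, 0.0709 and 0.0654), any shock-resistant replicate from 1 to 6 (0.154, 0.0568, 0.0702, 0.0543, 0.0804 and 0.0663) or shock-sensitive replicates 1, 3, 5 or 6 (0.0558, 0.0515, 0.0731 and 0.0667). C1h16orf92 lost it without shock-resistant replicate 1 (0.0599), and LOC102554555 without control replicate 4 (0.07) or shock-resistant replicates 1 or 5 (0.0599 and 0.0665). Far2 passed without shock-resistant replicate 6 (0.0325), Mthfd1l without control replicate 2 or shock-sensitive replicate 4 (0.0458 and 0.029), and Oog1 without control replicate 5 or shock-resistant replicate 2 (0.0356 and 0.0423).

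Among the clock genes, Bmal1 rose and 4 genes fell when adjusted over the list alone, while over all genes only Bmal1 of the 18 measured members passed. Bhlhe40, a repressor of clock transcription, differed by −0.35 ± 0.083 (SE, 6 of 6 arrays below the control median, limma adjusted p = 0.00519 over the list alone and 0.265 over all genes). Per2 and Per1, the period genes that inhibit BMAL1, differed by −0.31 ± 0.087 and −0.30 ± 0.11 (0.0144 and 0.0491 over the list, 0.272 and 0.335 over all genes, 6 of 6 arrays each). Nr1d2, a nuclear receptor of the clock chosen after the values were seen, was the other gene that fell over the list alone (−0.26, adjusted p = 0.0491). Nr1d1, a related repressor of Bmal1 also chosen after the values were seen, stood higher (0.28 ± 0.11, adjusted p = 0.058 over the list alone and 0.362 over all genes). As a set the clock list had a median of −0.06 with 5 members higher and 13 lower, and camera did not call it (adjusted p = 0.0898).

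Adjusted over the list alone, single members passed in 6 other lists, while 0 of them passed over all genes. In the DNA methylation list Mbd2, a reader of methylated DNA, differed by −0.20 ± 0.052 and Dnmt1, the maintenance methyltransferase, by −0.13 ± 0.04 (adjusted p = 0.0244 and 0.0424 over the list, 6 of 6 arrays below the control median). The other members past it were Hdac10, a histone deacetylase (0.19, limma adjusted p = 0.0348), Grin2c, an NMDA receptor subunit (0.41, adjusted p = 0.0259), and Txnrd1, the cytosolic thioredoxin reductase (−0.17, adjusted p = 0.0183). The peptides Nrtn, a GDNF-family factor, and Nmu, neuromedin U, were both below the negative control median (0.20 and 0.25, adjusted p = 0.04 and 0.0303). Their list partners by the naming rule, Hdac1 (−0.26), Grik1 (−0.52), Prdx5 (0.17), Fgf2 (−0.30) and Cort (0.23), did not pass.

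Camera called 0 of the 35 gene lists, with a smallest adjusted p of 0.0667 for cortical excitatory neuron markers (median −0.14, 3 higher and 16 lower) and 0.0792 for medium spiny neuron markers (0.36, 18 of 18 members higher). With an estimated correlation 0 lists passed (smallest adjusted p = 0.905) and 0 passed fry's directional test (0.658). Fry's mixed test, which asks whether members change in either direction and not whether they differ from other genes, passed for 2 lists, circadian clock (adjusted p = 0.000791) and DNA methylation (0.03). Median, mean and test differed in sign in 5 lists, none of them called. Camera called 10 lists without control replicate 1, 4 without control replicate 3 or shock-resistant replicate 3 or 4, and 3 without control replicate 2 or 6. It called 2 without shock-resistant replicate 1, and 1 without control replicate 4, shock-resistant replicate 2 or shock-sensitive replicate 6.

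**Figure D3:**
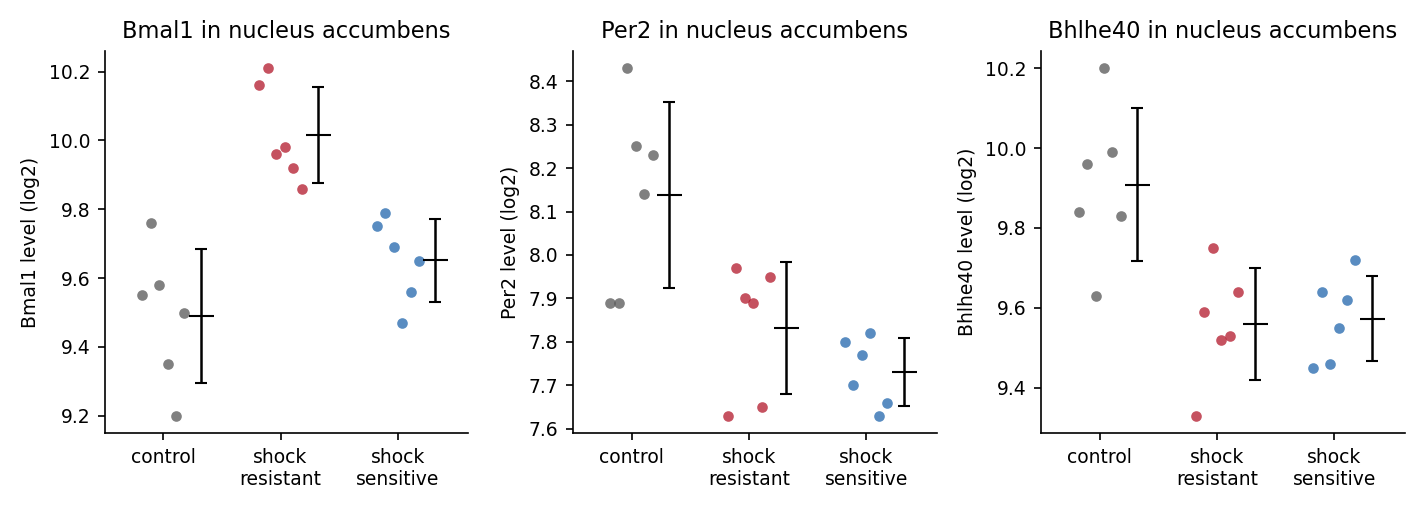
Log2 values of Bmal1, Per2 and Bhlhe40 (vertical axes) in the 6 arrays of each group (horizontal axis), 1 point per array with the group mean and SD as a line with bars. All 6 shock-resistant arrays lie above every other array for Bmal1, and the means of Per2 were 8.14 in controls, 7.83 in shock-resistant and 7.73 in shock-sensitive rats.

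The comparison of shock-sensitive rats with controls asks what differs in rats that took methamphetamine and reduced their intake under shock. Per2, which had the smallest p among lower genes, stood 1.33-fold below controls (−0.41 ± 0.087, SE, limma adjusted p = 0.403, 6 of 6 arrays below every control), at 7.73 ± 0.08 against 8.14 ± 0.21 (SD, n = 6 each). Bhlhe40 differed by −0.34 ± 0.083 (adjusted p = 0.425) and Ntmt2, a protein methyltransferase gene, by −0.50 ± 0.11 (0.403), each in 6 of 6 arrays below the control median. Ist1, a gene of membrane remodelling, stood 1.36-fold above controls (0.44 ± 0.097, adjusted p = 0.403), and Defb49 1.43-fold (0.51 ± 0.11, 0.403). Or6c33, an olfactory receptor gene, and Taar4, a trace amine receptor gene, were 0.57 ± 0.098 and 0.35 ± 0.061 higher (adjusted p = 0.214 each, 6 of 6 arrays above every control), both below the negative control median. Among microRNA genes Mir466c, Mir29b2 and Mir378 were higher by 0.43, 0.41 and 0.34. The rest named by the rule on the higher side, Xkr5 and the olfactory receptor genes Olr1088 and Or2g7, differed by 0.28 to 0.42. On the lower side Cdc34-ps1, Dppa3, Rbm24, Cables1, Vom1r81, St6gal1l and Tmem186 differed by −0.50 to −0.28.

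No gene passed limma's adjusted threshold (smallest adjusted p = 0.214), and 1345 had an unadjusted p under 0.05, 1008 higher and 337 lower. Quantile normalization made that split 542 and 531, and median centring 707 and 397. The nominal criterion took 59 genes, 36 higher and 23 lower, and 171 without control replicate 1, 112 without shock-sensitive replicate 1 and 103 without shock-sensitive replicate 2. With control replicate 3 left out, Ist1 alone passed (log2 difference 0.54, adjusted p = 0.00569).

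Immediate early genes, which neurons transcribe within minutes of activity, formed the list with the smallest camera p in shock-sensitive rats against controls. Their median was −0.19 with 23 of 28 members lower, and the list mean lay below the control median in 6 of 6 arrays (camera adjusted p = 1.03e-08, adjusted p = 0.321 with an estimated correlation). Dusp6, a phosphatase of ERK, and Fosl1, a FOS-family factor, differed by −0.20 and −0.14, and 0 members passed over all genes or adjusted over the list alone. The clock list was called lower (median −0.16, 14 of 18 lower, 5 of 6 arrays, adjusted p = 1.7e-06, and 0.327 with an estimated correlation). Adjusted over the list alone 4 clock genes fell and 0 over all genes. These were Per2 (limma adjusted p = 0.00333), Bhlhe40 (0.00746), Per1 (−0.34 ± 0.11, 0.0296) and Cry1, the cryptochrome repressor (−0.18 ± 0.06, 0.0416), each below the control median in 6 of 6 arrays. The CRH and glucocorticoid list was called lower (−0.067, 12 of 17 lower, 5 of 6 arrays, adjusted p = 0.00459), as was DNA methylation (−0.037, 12 of 16, 5 of 6 arrays, 0.00522), each with adjusted p = 0.321 with an estimated correlation. In these Hsd11b1, which regenerates corticosterone, differed by −0.19, Mbd4 by −0.088 and Mbd2 by −0.18, the last with a limma adjusted p = 0.0451 over the list alone.

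Markers of medium spiny neurons were called lower as well (median −0.21, 18 of 18 members, list mean below the control median in 4 of 6 arrays, adjusted p = 0.00459), with Bcl11b and Pde2a at −0.29 and −0.23. Voltage-gated calcium and sodium channels were called lower (−0.084, 16 of 22, 4 of 6 arrays, 0.0135), with Cacna1c and Cacnb1 at −0.19 and −0.18. Ribosomal protein genes were called lower at a median of −0.057 (39 of 49, 0.000586), although the list mean lay below the control median in 2 of 6 arrays, and Rps25 and Rpl3 stood at −0.25 and −0.11. Oxidative phosphorylation genes were called lower at −0.024 (27 of 45, 3 of 6 arrays, 0.0466), with Cox5b and Ndufa2 at −0.19 and −0.18. Called higher were genes of blood cells (0.29, 7 of 8, 6 of 6 arrays, 0.0119), myelinating oligodendrocytes (0.13, 16 of 20, 3 of 6, 0.0238) and microglia (0.11, 18 of 19, 4 of 6, 0.0449). Their named members were Hba-a1 and Alas2, of haemoglobin and haem synthesis (0.58 and 0.47), Gpr37 and Fa2h (0.32 and 0.24), and P2ry12 and Itgam (0.39 and 0.28). With an estimated correlation the adjusted p was 0.859 for oxidative phosphorylation and 0.773 for the other 6 lists of this paragraph. Fry's directional test called 0 lists (smallest adjusted p = 0.558) and its mixed test 1, the clock list (0.0137).

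Quantile normalization ended the calls of CRH and glucocorticoid signalling (adjusted p = 0.0618), calcium and sodium channels (0.473), oxidative phosphorylation (0.926), ribosomal proteins (0.0845) and medium spiny neurons (0.0773). With the medium spiny neuron marker mean as a covariate, added after seeing the data, calcium and sodium channels were not called (0.407, median −0.084 to −0.015). Oligodendrocytes (0.157, 0.126 to 0.087) and microglia (0.0725, 0.108 to 0.092) were not called either but kept most of their medians. The medium spiny neuron call ended by construction (0.688), since the covariate is that list's mean. Genes at or above the median level alone ended the calls of channels (0.207), oxidative phosphorylation (0.924), ribosomal proteins (0.0562) and medium spiny neurons (0.0555). The first residual principal component as a covariate ended that of oxidative phosphorylation (0.0501). Without control replicate 1 and shock-sensitive replicate 4 together, also added after seeing the data, oxidative phosphorylation (0.465), ribosomal proteins (0.465, median 0.014) and microglia (0.143) were not called. The number of lists called was 11, and was 6 without shock-sensitive replicate 4 and 7 without control replicate 5 or 6. Immediate early, clock and CRH lists kept their calls with any 1 array left out, the last with medians of −0.02 without control replicate 3 and −0.041, −0.042 and −0.044 without shock-sensitive replicates 1, 3 and 5. DNA methylation was lost without shock-sensitive replicate 4 (adjusted p = 0.13) and its median was −0.058 without replicate 2. Medium spiny neuron markers were lost without control replicate 3 or 6 (0.1 and 0.069) or shock-sensitive replicate 4 (0.754, median 0.011), and their median was −0.45 without control replicate 1 and −0.32 without shock-sensitive replicate 1. Calcium and sodium channels were lost without control replicates 3, 5 or 6 (0.0839, 0.124 and 0.144) or shock-sensitive replicate 4 (0.676), with medians of −0.17 without control replicate 1 and −0.14 without shock-sensitive replicate 1. Ribosomal proteins were lost without control replicate 1 (0.195, median 0.013) or shock-sensitive replicate 3 (0.73, median 0.032), and read −0.11 and −0.097 without control replicates 2 and 4, and −0.10 and −0.098 without shock-sensitive replicates 1 and 5. Oxidative phosphorylation was lost without control replicates 1, 3 or 5 (0.383, 0.178 and 0.0731), shock-resistant replicates 1, 2, 3 or 6 (0.0508, 0.0507, 0.05 and 0.0618) or shock-sensitive replicates 1, 3 or 4 (0.0837, 0.445 with a median of 0.038, and 0.11), and read −0.048 and −0.037 without control replicates 4 and 6 and −0.069 without shock-sensitive replicate 2. Oligodendrocytes were lost without control replicates 4, 5 or 6 (0.297, 0.0921 and 0.171) or shock-sensitive replicates 2, 4 or 5 (0.132, 0.252 and 0.418), with a median of 0.19 without control replicate 1. Microglia were lost without control replicates 2, 5 or 6 (0.175, 0.115 and 0.125), shock-resistant replicate 6 (0.0526) or shock-sensitive replicates 1, 2, 4 or 5 (0.16, 0.132, 0.252 and 0.179), and blood cells without shock-sensitive replicate 5 (0.142, median 0.18). Median, mean and test differed in sign in 13 lists, none of them called.

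The direct comparison of shock-resistant with shock-sensitive rats asks what separates rats that differ in drug taking under punishment. Fst, which encodes the activin-binding protein follistatin, stood 1.38-fold higher in shock-resistant rats (0.46 ± 0.07, SE, limma adjusted p = 0.0852), at 6.91 ± 0.18 against 6.45 ± 0.07 (SD, n = 6 each), with 6 of 6 arrays above every shock-sensitive array. Mapk4, an atypical MAP kinase gene, stood 1.93-fold higher (0.95 ± 0.22, adjusted p = 0.664), Reln 1.88-fold (0.91 ± 0.20, 0.647) and Pmepa1, an inhibitor of TGF-beta signalling, 1.79-fold (0.84 ± 0.20, 0.664), each in 6 of 6 arrays above every shock-sensitive array. Far2 stood 1.6-fold higher, Ptprn 1.38-fold and Bmal1 1.28-fold (adjusted p = 0.361, 0.396 and 0.664). Zdhhc2, a palmitoyltransferase, Dusp18 and Tmem30b were 0.27 to 0.30 higher. Zfp612, a zinc finger gene, stood 1.4-fold lower (−0.48 ± 0.09, adjusted p = 0.346) and Ist1 1.36-fold lower (−0.45 ± 0.097, 0.647), in 6 of 6 arrays below every shock-sensitive array. Mir29a differed by −0.90 ± 0.21, from a level below the negative control median, and Mir29b2 by −0.37. Tubb4a, a tubulin of myelinating cells, differed by −0.45, and Htr5a, a serotonin receptor, by −0.28. Or6c33, Mir3559, Frmd4a and Insl5 were the others named on the lower side, at −0.43 to −0.28.

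No gene passed limma's adjusted threshold (smallest adjusted p = 0.0852), and 1415 had an unadjusted p under 0.05, 582 higher and 833 lower, a split that median centring turned to 874 and 630. Without shock-resistant replicate 4 Fst passed (0.51, adjusted p = 0.0154), and without control replicate 3 Ist1 did (0.0365). With the first residual principal component as a covariate 239 genes passed, Fst among them (log2 difference 0.461 ± 0.065, adjusted p = 0.00327). That component is made from the residuals of the same fit, so it leaves the differences as they are and takes up residual variance by construction. The p-values of this setting may thus be too small, and its 239 calls are not evidence of differences. It lowered the standard error of 12379 genes (0.07 to 0.065 for Fst and 0.224 to 0.123 for Mapk4) and raised that of 9714. Over 12 alternatives Fst passed in this 1 alone (adjusted p = 0.00327 to 0.538). The nominal criterion took 248 genes, 117 higher and 131 lower, and 101 without shock-sensitive replicate 4, 477 without shock-sensitive replicate 1 and 151 without shock-resistant replicate 1. With the marker mean of medium spiny neurons as a covariate, added after seeing the data, it took 52, of which 39 were among the 248.

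Markers of medium spiny neurons were the list with the smallest p, called higher in shock-resistant rats at a median of 0.59 with 18 of 18 members and 6 of 6 arrays above the shock-sensitive median (camera adjusted p = 1.06e-08, and 0.597 with an estimated correlation). Adcy5, their adenylyl cyclase, and Foxp1, a transcription factor of these cells, differed by 0.76 ± 0.31 and 0.71 ± 0.28. Indirect pathway markers, Penk and Gpr52 (0.62) among them, were called higher (median 0.28, 7 of 10, 6 of 6 arrays, adjusted p = 0.00995, and 0.597 with an estimated correlation). Direct pathway markers were not called (0.14, adjusted p = 0.0624), and neither was the dopamine list (−0.005, 0.566), in which Drd1, Drd2 and Ppp1r1b, chosen after the values were seen, stood 0.64, 0.69 and 0.68 higher. Called lower were markers of cells outside this class, astrocytes (−0.12, 17 of 19 members, adjusted p = 0.00405), myelinating oligodendrocytes (−0.16, 18 of 20, 0.00226), oligodendrocyte precursors (−0.12, 12 of 13, 0.0196), blood cells (−0.25, 7 of 8, 0.0263), cortical excitatory neurons (−0.14, 15 of 19, 0.0208) and hypothalamic and septal neurons (−0.21, 16 of 21, 0.0433). Their list means lay below the shock-sensitive median in 5 of 6 arrays, and in 6 of 6 for the neuron lists. With an estimated correlation the adjusted p was 0.597 for astrocytes, precursors and blood cells and 0.598 for the other 3. Slc17a6, the glutamate transporter of subcortical neurons, differed by −1.02 ± 0.41, Irs4 by −0.34, Tbr1, a cortical transcription factor, by −0.56 and Rorb by −0.14. Among glia Lhfpl3 differed by −0.52 ± 0.14 (adjusted p = 0.0263 over its list alone), Gpr17 by −0.28, Sox9 by −0.26, Slc4a4 by −0.17, Tspan2 by −0.25 and Septin4 by −0.20, and among blood genes Alas2 by −0.40 and Ahsp by −0.15. Choroid plexus genes were called higher (0.25, 12 of 17, 0.0263, and 0.598 with an estimated correlation) while the list mean exceeded the shock-sensitive median in 1 of 6 arrays, with Rarres2 and Sostdc1 at 0.32 and 0.47. Sostdc1 read 7.33 in shock-resistant replicate 4 and at most 5.61 in the other shock-resistant arrays.

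Lists of neuronal function were called beside these markers. Voltage-gated calcium and sodium channels were higher (median 0.20, 16 of 22, 5 of 6 arrays, adjusted p = 0.000221, and 0.597 with an estimated correlation), and adjusted over the list alone Cacna1i and Cacna1a, T-type and P/Q-type calcium channels, rose (0.60 ± 0.16 and 0.33 ± 0.098, adjusted p = 0.0273 and 0.0378). Ribosomal protein genes were called higher (0.10, 46 of 49, 1.73e-05, and 0.598 with an estimated correlation) though in 3 of 6 arrays, with Rps16 and Rplp1 at 0.23 and 0.20. Immediate early genes were called higher (0.13, 20 of 28, 4 of 6 arrays, 0.0093, and 0.598 with an estimated correlation), with Nr4a3 and Homer1 at 0.68 ± 0.24 and 0.66 ± 0.20. The clock list was called higher (0.057, 15 of 18, 6 of 6 arrays, 0.0196, and 0.598 with an estimated correlation), and Bmal1 rose adjusted over the list alone (adjusted p = 0.00926). GABA receptor genes were called lower (−0.11, 11 of 17, 5 of 6 arrays, 0.0373), with Gabra3 and Gabrb1 at −0.61 ± 0.19 and −0.37, and interferon genes higher (0.048, 20 of 27, 4 of 6 arrays, 0.0237), with RT1-Da and Cxcl10 at 0.23 and 0.17. Both had adjusted p = 0.597 with an estimated correlation. Adjusted over the list alone Htr1b, a serotonin receptor, rose (0.63 ± 0.18, limma adjusted p = 0.0277) while Htr5a and Chrna4, a nicotinic subunit, fell (−0.28 and −0.46, 0.0238 and 0.0384). Dnajb5, a heat shock protein gene, rose (0.52 ± 0.14, 0.0375) and Kcnt2, a sodium-activated potassium channel, fell (−0.53 ± 0.15, 0.0457) adjusted over their lists alone, while Kcnj6 and Hsph1 stood at −0.77 and 0.33. Over all genes 0 of these passed. Fry called 0 lists by either test (smallest directional adjusted p = 0.523).

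Besides the opioid, direct pathway and dopamine lists, those that camera did not call here were heat shock and unfolded protein response (0.021, adjusted p = 0.0642), serotonin and acetylcholine receptors (−0.064, 0.0996), pericytes, smooth muscle and fibroblasts (0.048, 0.129), striatal interneurons (−0.043, 0.18) and ionotropic glutamate receptors (0.059, 0.339). Calcium-activated and inward rectifier potassium channels (−0.022, 0.538), histone deacetylases and acetyltransferases (−0.014, 0.538), endothelial cells (0.036, 0.566) and neurotrophic factors (−0.026, 0.585) followed. Last came other neuropeptides (−0.03, 0.603), metabotropic glutamate receptors (0.046, 0.606), antioxidant defence (−0.019, 0.606) and voltage-gated potassium channels (−0.098, 0.772). Microglia (−0.068, 0.0788), DNA methylation (0.039, 0.251), oxidative phosphorylation (0.04, 0.264) and CRH and glucocorticoid genes (−0.035, 0.585), called in shock-sensitive rats against controls, were not called between the methamphetamine groups. Median, mean and test differed in sign in 4 lists, none of them called.

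With the medium spiny neuron marker mean as a covariate, added after seeing the data, the call of that list ended by construction (adjusted p = 0.658), and 10 of the other 14 calls ended with it. Medians shrank for channels (0.198 to 0.014, adjusted p = 0.575), indirect pathway (0.276 to 0.045, 0.518), astrocytes (−0.12 to −0.051, 0.154), oligodendrocytes (−0.156 to −0.034, 0.296) and precursors (−0.118 to −0.014, 0.296). Those of the clock (0.057 to −0.014, adjusted p = 0.658) and of hypothalamic and septal neurons (−0.205 to 0.055, 0.0806) turned in sign. GABA receptors (−0.11 to −0.085, adjusted p = 0.0806), interferon (0.048 to 0.045, 0.0806) and blood cells (−0.249 to −0.218, 0.0732) lost their calls with most of their medians kept, so for these the covariate removed little of the difference. Quantile normalization ended the calls of interferon and choroid plexus genes (0.0509 each), and median centring that of choroid plexus genes (0.0652). Genes at or above the median level alone ended the calls of GABA receptors (0.133), interferon (0.107), cortical neurons (0.497), hypothalamic and septal neurons (0.0736), precursors (0.0736) and blood cells (0.107). The first residual principal component as a covariate ended those of cortical neurons (0.0816), blood cells (0.0676) and choroid plexus genes (0.0676). Without control replicate 1 and shock-sensitive replicate 4 together, chosen after seeing the data, hypothalamic and septal neurons (0.46, median −0.053) and astrocytes (0.052) were not called. Medium spiny neuron and channel lists kept their calls with any 1 array left out, with medians of 0.34 and 0.12 without shock-sensitive replicate 4. With shock-resistant replicate 4 left out, 7 lists were called, with immediate early (adjusted p = 0.07), GABA (0.0633), clock (0.07), interferon (0.0633), indirect pathway (0.0594), cortical (0.0516), hypothalamic (0.0836) and choroid plexus genes (0.208, median −0.08) lost and an astrocyte median of −0.18. Shock-resistant replicate 1 ended GABA (0.131), interferon (0.0923), hypothalamic (0.262) and precursor calls (0.124) when left out, with an indirect pathway median of 0.18, and replicate 2 ended GABA (0.07), hypothalamic (0.0643) and blood (0.07). Without shock-resistant replicate 5 the cortical call was lost (0.091), and without replicate 6 GABA (0.0943) and interferon (0.0836), with an astrocyte median of −0.074. Without shock-sensitive replicate 1 the immediate early call was lost (0.146) and the clock median was 0.10, and without replicate 2 GABA (0.109), interferon (0.103) and choroid plexus (0.128) were lost and the clock median was 0.10. Shock-sensitive replicate 3 ended the ribosomal (0.489, median 0.006), cortical (0.12), hypothalamic (0.135) and choroid plexus calls (0.0505). Shock-sensitive replicate 4 ended the clock (0.0649), hypothalamic (0.621, median −0.053), astrocyte (0.0508, median −0.064) and precursor calls (0.0508, median −0.051), with an indirect pathway median of 0.13. Without shock-sensitive replicate 5 the clock (0.11), oligodendrocyte (0.0604, median −0.083) and blood calls (0.185, median −0.13) were lost and the precursor median was −0.069, and without replicate 6 the clock (0.0866) and cortical calls (0.18) were lost.

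**Figure D4:**
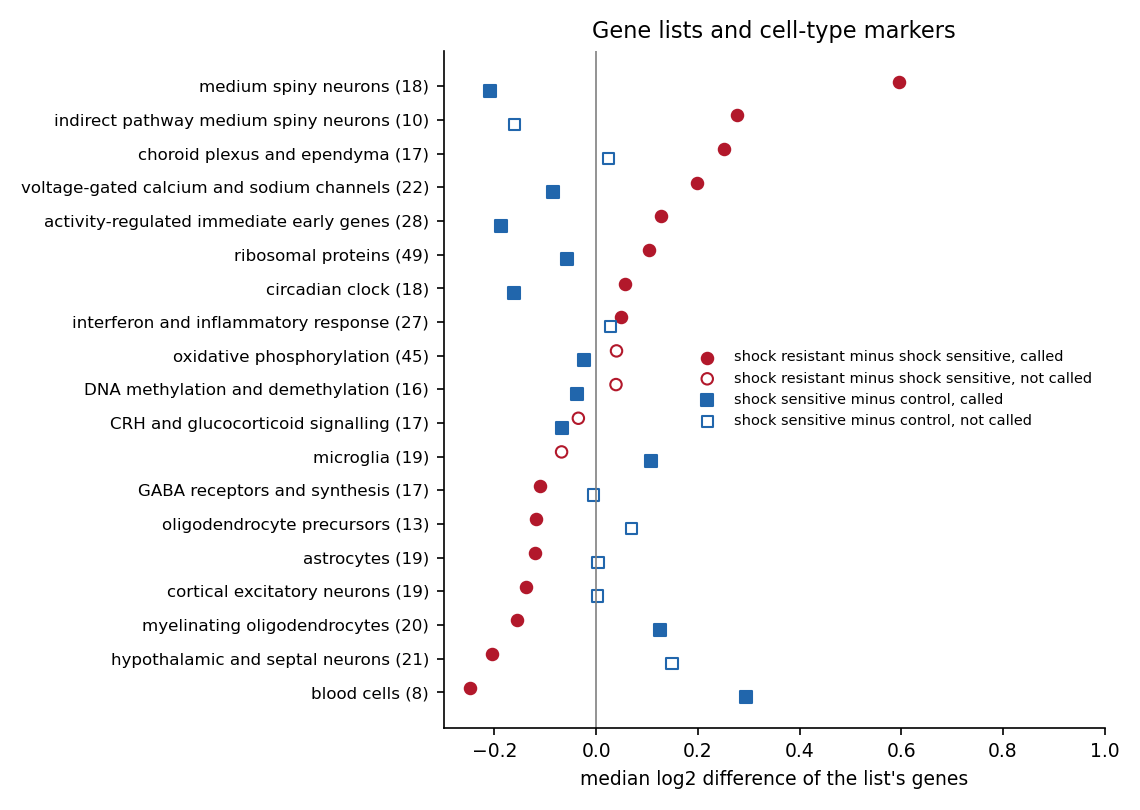
Median log2 difference of each gene list (horizontal axis) for the lists called by camera in at least 1 of the comparisons drawn (vertical axis). The comparisons drawn are shock resistant against shock sensitive and shock sensitive against control, with 1 symbol per comparison, filled where camera called the list. Medium spiny neuron markers lie at 0.59 between the methamphetamine groups and −0.21 in shock-sensitive rats against controls.

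The mean of both methamphetamine groups against controls asks what the drug-taking rats share, and the moderated F test asks for any difference among the 3 groups. C1h16orf92 rose by 0.25 ± 0.034 (SE, limma adjusted p = 0.019), with 12 of 12 methamphetamine arrays above every control, and was the only gene past the threshold. It was chosen after the values were seen and read below the negative control median. Among clock genes 2 rose and 6 fell adjusted over the list alone, while 0 passed over all genes. Bmal1 and Nr1d1 rose (0.35 ± 0.074 and 0.25, limma adjusted p = 0.00115 and 0.0443). The rise of Bmal1 came mostly from shock-resistant rats, with a mean of 10.01 against 9.65 in shock-sensitive rats and 9.49 in controls. Per2, Bhlhe40, Per1, Per3, Nr1d2 and Cry1 fell (−0.36, −0.34, −0.32, −0.34, −0.21 and −0.13). Nr1d1, Per3 and Nr1d2 were chosen after the values were seen. Mbd2 fell over the DNA methylation list alone (limma adjusted p = 0.00968) and Per1 over the CRH and glucocorticoid list alone (adjusted p = 0.0476).

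Camera called 3 lists, all lower. These were immediate early genes (median −0.10, 23 of 28 members, 10 of 12 arrays below the control median, adjusted p = 5.68e-05), the clock (−0.12, 14 of 18, 11 of 12, 0.000965) and CRH and glucocorticoid genes (−0.079, 12 of 17, 10 of 12, 0.0197), each with adjusted p = 0.906 with an estimated correlation. Fry's directional test called 0 (smallest adjusted p = 0.748) and its mixed test 1, the clock (0.000567). Quantile normalization ended the clock (0.117) and CRH calls (0.164), and genes at or above the median level alone that of CRH (0.127). The CRH call was lost without control replicate 3 (0.0972), shock-resistant replicate 3 (0.0568) or shock-sensitive replicates 2 or 5 (0.0617 and 0.0549), the immediate early median was −0.054 without control replicate 2, and the clock median −0.08 without control replicate 3. Lists called numbered 12 without control replicate 1, 6 without control replicate 2 and 5 without shock-sensitive replicate 3. Median, mean and test differed in sign in 9 lists, none of them called.

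At an unadjusted p under 0.05 the mean of both groups took 2156 genes, 1580 higher and 576 lower, and 797 and 791 after quantile normalization. The nominal criterion took 49 genes, 27 higher and 22 lower, and 27 without shock-resistant replicate 1, 80 without control replicate 1 and 77 without control replicate 3. C1h16orf92 lost its call without control replicates 1, 2, 3, 5 or 6 (adjusted p = 0.0503, 0.111, 0.0751, 0.0662 and 0.0763), shock-resistant replicate 2 (0.05) or shock-sensitive replicate 5 (0.0518), and passed under 5 of 10 alternatives (0.0102 to 0.0902). The 5 include the first residual principal component as a covariate, whose p-values may be too small (limma adjusted p = 0.0246). They also include the mean of features, which left the difference as it was (0.0186). With control replicate 4 or shock-sensitive replicate 2 left out, 2 genes passed. The F test called 2 genes, C1h16orf92 and LOC102554555 (adjusted p = 0.0317 each), with 1902 at an unadjusted p under 0.05. The other genes with the smallest p were Fst and Defb49 (adjusted p = 0.0826), Bmal1, Far2, Npbwr1l1, Oog1 and Or6c33 (0.129), Mthfd1l (0.162), Taar4 (0.164) and Ptprn (0.177). It called 169 genes with the first residual principal component as a covariate, 3 without shock-resistant replicate 4 and 1 without shock-sensitive replicate 1. It called 0 without control replicates 1, 2, 4, 5 or 6, shock-resistant replicates 1, 2, 3, 5 or 6, or shock-sensitive replicates 3, 4, 5 or 6.

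Differences of the 2 methamphetamine groups from controls were compared across the 22093 genes, which are not independent replicates. Their correlation was 0.403, and unchanged groups simulated against the same controls gave 0.469 on average (−0.0877 to 0.907 in 100 simulations). The covariance was 0.00494 against a simulated 0.00479 (SD 0.00348). With the controls split 3 and 3 between the comparisons the correlation was 0.00228 (−0.223 to 0.232 over 20 splits) and the covariance −0.000282. Nominal calls shared by both comparisons numbered 9 higher and 3 lower, where independent lists give 0.132 and 0.0979. Unchanged groups simulated against shared controls gave 3.55 higher and 3.7 lower on average (0 to 68 and 0 to 44), and as many as were seen in 11 and 30 of 100 simulations.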

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

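In this part the tests of the hour of collection and of control replicate 2 were chosen only after the result was seen, and all marker covariate fits were added to the set of alternatives after seeing the data. Arrays were singled out where the gap to the nearest array of the same group of 6, divided by the group's range, exceeded Dixon's critical value. Of 492 groups tested 57 held such an array, where chance gives about 1 in 20, or 25, if groups are independent. They are not, since genes and lists vary together over the same arrays. In addition 381 of the groups were of single genes, many of them named for a small p in the same data. The 25 is therefore only a rough guide. Control replicate 1 accounted for 20 of the 57, shock-sensitive replicate 4 for 6, and control replicate 2 and shock-resistant replicate 4 for 5 each.

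Pdyn and Penk were higher in shock-resistant than in shock-sensitive rats, by 1.10 and 0.65 on the log2 scale, in a comparison where the 18 medium spiny neuron markers were higher too, 1 of which, Ppp1r1b, is also in the dopamine list while neither Pdyn nor Penk is among the 18. With the marker mean as a covariate the difference of Pdyn was 0.632 ± 0.36 (SE), between 1 and 2 standard errors, so the striatal tissue share of the dissection and a response of the neurons cannot be told apart for it. For Penk it was 0.318 ± 0.156, past 2 standard errors by a narrow margin, and for Pdyn against controls 0.844 ± 0.34, also past 2. The marker mean is an indirect measure of 1 cell class, so the fit may correct too little. These remainders therefore do not exclude tissue share as the cause of either. A single array is argued against, since the smallest difference with 1 array left out was 0.909 for Pdyn and 0.539 for Penk. A biological difference between the groups, in drug intake or response to shock, remains open and may act together with tissue share.

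Bmal1 rose in shock-resistant rats by 0.53 while period genes and Bhlhe40 read lower in both methamphetamine groups. With the marker covariate the difference went from 0.526 ± 0.085 to 0.492 ± 0.085 (SE), which ended the call (limma adjusted p = 0.079, and 0.00537 to 0.185 over the alternatives). The difference changed little, which argues against tissue share, as far as these markers measure it, as the whole cause. The 10 clock genes driven in opposite phase had a median of −0.163 in shock-resistant rats against controls, as another hour of collection could give. The standard error over these genes was 0.059, which treats genes of the same rats as independent. They did not move as 1 phase, since Nr1d1 was 0.28 higher and Dbp, Tef and Ciart stood at −0.14, −0.014 and −0.032. In shock-sensitive rats against controls all of the 10 but Nr1d1 (0.227) read lower too, with Per1, Per2 and Per3 at −0.344, −0.41 and −0.349. Bmal1 averaged 9.65 there, against 9.49 in controls and 10.01 in shock-resistant rats. The lower values of these genes thus did not follow the rise of Bmal1 between the methamphetamine groups. A drug effect on the clock could also change these genes. Since the hour is not given in the sources used here, hour of collection and drug effect cannot be told apart.

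Immediate early genes were lower in shock-sensitive rats than in controls, with a median of −0.19. Camera called the list at the preset correlation, but not with an estimated correlation (adjusted p = 0.321). Without control replicate 2, which had the highest list mean, the median was −0.133. The standard error over members was 0.045 in the fit with all arrays, and it treats genes of the same rats as independent. The part this array plays remains undecided. The marker covariate left −0.153, which argues against tissue share, as far as these markers measure it, as the whole cause. Handling before tissue collection, activity of the accumbens and the drug history may each lower these genes, and none of them was tested.

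For shock-resistant rats against controls 4 genes passed the adjusted threshold. As many did in 2 of 100 random splits of the arrays, the real one included, with 12 as the highest other. As many nominal genes (175) arose in 4 of 100, with 246 as the highest other. Few splits reached these counts, but other splits went past both. The shares were also not adjusted over the counts tested, so chance is not excluded for either. Few splits likewise reached the count of the mean of both methamphetamine groups (1 gene, 2 of 100 splits, highest other 1). In the F test only the real split gave as many (2 genes, 1 of 100, highest other 0). Unadjusted shares for counts this small do not exclude chance. A count of 0 is reached by 100 of 100 splits whatever the groups, so the splits decide nothing on adjusted counts of shock-sensitive rats against controls (0, highest other 143) and of the 2 methamphetamine groups (0, highest other 6), or on lists in shock-resistant rats against controls (0, highest other 17). Chance cannot be excluded for nominal counts of shock-sensitive rats against controls (59, 45 of 100, highest other 556), of the methamphetamine groups against each other (248, 7 of 100, highest other 563) and of their mean (49, 35 of 100, highest other 304). For lists called, as many arose in 25 of 100 splits for shock-sensitive rats against controls (11, highest other 21), 5 for the methamphetamine groups (15, highest other 18) and 98 for their mean (3, highest other 17), so chance cannot be excluded for these 3. In each of the 4 contrasts the other splits called a median of 8 lists. Splits that call 143 genes where the real one calls 0, or 556 nominal ones where it calls 59, point to a structure of the samples that the groups do not follow.

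Control replicate 1 stood apart from the other controls in gene values, reading low for Oprd1 (6.42), Pde2a (13.82), Bcl11b (10.59), Homer1 (11.76), Adcy5 (13.07) and Gpr52 (8.95). It read high for Oprl1 (9.62), Grik1 (8.74), Txnrd1 (9.79), St6gal1l (5.56), Ndufa2 (7.81) and Slc17a6 (9.05). Its list means were low for ionotropic glutamate receptors (10.22), voltage-gated potassium channels (10.05), calcium and sodium channels (10.81), the clock (9.55) and medium spiny neurons (11.3), and high for hypothalamic and septal neurons (7.39). Its correlation with the mean of the other arrays was 0.996 and its root mean square deviation from the group mean 0.231.

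Control replicate 2 was high for Dusp6 (7.06), Nr4a3 (8.59), Dnajb5 (9.83) and the means of the opioid (9.3) and immediate early lists (7.88). Control replicate 3 was low for Ppfia2 (11.19) and Kcnt2 (7.88) and high for Ist1 (10.19), Zfp612 (9.47), and the interferon (5.92) and endothelial list means (8.4). Control replicate 4 was high for Sostdc1 (5.51) and Npbwr1l1 (6.24).

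Among shock-resistant arrays replicate 4 was high for Ttr (16.58), Sostdc1 (7.33), RT1-Da (5.47) and the choroid plexus (8.44) and CRH list means (8.59). Replicate 6 was high for Gdf9 (4.56) and low for the serotonin and acetylcholine (7.55) and voltage-gated potassium channel means (10.12). Prdx5 was high in replicate 1 (8.15), Htr1b high in replicate 2 (9.49) and Rarres2 low in replicate 5 (7.06).

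Among shock-sensitive arrays replicate 4 was high for Gcnt4 (6.0) and the hypothalamic and septal list mean (7.65), and low for Tmem30b (3.64), Cacna1a (10.42), the calcium and sodium channel mean (10.77) and the correlation with the mean of the other arrays (0.996). Replicate 3 was high for Nmu (5.79) and Vom1r81 (4.33) and low for Rps25 (10.04) and the oxidative phosphorylation mean (10.28). Nrtn was low in replicate 1 (5.88), Htr1b high in replicate 2 (8.91) and Dnmt1 high in replicate 6 (8.45).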

How the results depend on the processing

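Added after seeing the data were the marker covariate and the fit without control replicate 1 and shock-sensitive replicate 4. With settings other than leaving out 1 array, 1832 values of single genes and lists stayed on their side of the threshold. Of the others 149 fell behind it, 37 passed it and 19 reversed. The 1832 include genes not called in the main fit that stayed uncalled, so they do not measure how stable the calls were. Only results called in the main fit could be among the 149. Of the values that answer a comparison 158 stayed, 66 moved and 2 reversed. Pdyn and Penk kept their direction in shock-resistant rats against both other groups in every setting run. Signal over background limits the call of 3 of the 4 genes past the threshold in shock-resistant rats, which lie below the negative control median. Where a value below moved or reversed, the cause was not tested unless it is stated.

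Changing the fold moved the nominal counts by construction. For shock resistant against control, shock sensitive against control, the 2 methamphetamine groups and their mean against control they were 565, 244, 512 and 253 at 1.2-fold and 37, 12, 72 and 7 at 1.5-fold. Over all features, a larger set, they were 868, 522, 561 and 444, with adjusted counts of 0 in shock-resistant rats, 2 in the mean and 0 in the F test. Genes at or above the median level gave adjusted counts of 0, 0 and 0 for the same 3, nominal counts of 39 in shock-sensitive rats and 31 in the mean, and 5 lists each in shock-resistant rats and the mean. Only the 2 groups compared in the fit, with fewer arrays, gave 0 genes in shock-resistant rats. Quantile normalization gave 0 in the mean and the F test, 5, 6 and 1 lists in shock-resistant rats, shock-sensitive rats and the mean, and Pomc −0.011 in shock-sensitive rats against controls. Median centring gave 0 and 0 genes in the mean and the F test, 1 list in shock-resistant rats and Oprk1 −0.004 in shock-sensitive rats. Trend and robust estimation gave 2 genes in the mean. Array weights gave 9 genes in shock-resistant rats, 3 in the mean and 5 in the F test, 149 nominal in shock-sensitive rats, and reversed Oprd1 (−0.045) and Pnoc (0.11) in shock-resistant and Oprk1 (−0.073) and Pdyn (−0.023) in shock-sensitive rats against controls. The first residual principal component gave 25, 1, 239 and 2 genes in the 4 contrasts, 169 in the F test and 4 lists in shock-resistant rats. These gene counts may be too high, since the component takes up residual variance by construction. An estimated correlation and fry's directional test each called 0 lists in shock-sensitive rats, between the methamphetamine groups and in the mean, and fry's mixed test 2, 1, 0 and 1 in the 4 contrasts. Splitting the controls gave a correlation of 0.002 between comparisons.

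The marker covariate gave 2 genes in the mean and 0 in the F test, 8 lists in shock-resistant rats against controls and 7 between the methamphetamine groups, and 52 nominal genes there. It reversed Oprd1 (−0.10), Oprl1 (0.023) and Pnoc (0.12) in shock-resistant rats against controls, Oprd1 (0.058), Oprl1 (−0.018) and Pnoc (−0.018) in shock-sensitive rats, and Oprd1 (−0.16), Oprl1 (0.041), Pnoc (0.14), the clock list (−0.014) and the hypothalamic and septal list (0.055) between the methamphetamine groups. Without control replicate 1 and shock-sensitive replicate 4 together there were 0 genes in the mean and the F test, 10 and 9 lists in shock-resistant rats and the mean, and 107, 134 and 77 nominal genes in shock-sensitive rats, between the methamphetamine groups and in the mean. Oprd1 (−0.12) and Pnoc (0.13) reversed in shock-resistant and Oprk1 (−0.072) and Pdyn (−0.057) in shock-sensitive rats.

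Leaving out 1 array at a time gave adjusted counts of 0 to 7 in shock-resistant rats, 0 to 1 in shock-sensitive rats and between the methamphetamine groups, 0 to 2 in the mean and 0 to 3 in the F test. Nominal counts ran from 105 to 249, 53 to 171, 101 to 477 and 27 to 80, and lists called from 0 to 10, 6 to 15, 7 to 17 and 2 to 12 in the 4 contrasts. Pdyn in shock-sensitive rats against controls ran from −0.19 to 0.34, Oprd1 from −0.27 to 0.002, Oprk1 from −0.11 to 0.14, Oprl1 from −0.05 to 0.28, Oprm1 from −0.075 to 0.037 and Pnoc from −0.008 to 0.28. In shock-resistant rats Oprd1 ran from −0.12 to 0.14 and Pnoc from −0.16 to 0.13. The choroid plexus list between the methamphetamine groups ran from −0.08 to 0.33, and in shock-sensitive rats oxidative phosphorylation from −0.069 to 0.038 and ribosomal proteins from −0.11 to 0.032.

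Replicate numbers are shared by the groups but are not said to pair rats. Over 18 same-numbered pairs the deviations correlated at −0.313 to 0.295, with a mean of 0 against 0.001 for other numbers. Of these pairs 5 were over 0.1. In 6 of the 18 the array of 1 group was closest to its own number among the 6 arrays of the other group. That is more than the 1 in 6 that chance gives. The mean of 0 shows no pairing by number on average, but a factor shared within some numbers is not excluded. The replicate block gave 2 genes in shock-resistant rats against controls, of which 1 was among the 4, and ended the list calls of oxidative phosphorylation in shock-sensitive rats (adjusted p = 0.0566) and of hypothalamic and septal neurons between the methamphetamine groups (0.0578). In the mean of both methamphetamine groups C1h16orf92 lost its call under the block (limma adjusted p = 0.084) and 1 other gene passed.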

Other observations

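Besides cortical, medium spiny neuron and clock genes, 8 gene lists had a camera adjusted p between 0.0792 and 0.126 in shock-resistant rats against controls, and none was called. GABA receptor genes had a median of −0.12 there with 12 of 17 members lower (camera adjusted p = 0.0792), and serotonin and acetylcholine receptors −0.11 (14 of 24 lower, 0.0792). Immediate early genes stood at −0.075 with 20 of 28 lower (0.0792, and 0.662 with a median of −0.028 without control replicate 2), CRH and glucocorticoid genes at −0.099 with 11 of 17 lower (0.0898) and astrocytes at −0.057 with 14 of 19 lower (0.103). Interferon and inflammatory genes stood at 0.095 with 22 of 27 members higher (0.0792), and genes of pericytes, smooth muscle and fibroblasts at 0.066 with 15 of 18 higher (0.0898, and 0.436 with 0.041 without shock-resistant replicate 4). Choroid plexus genes had a median of 0.23 with 15 of 17 higher (0.126), which rested on shock-resistant replicate 4, since without it the median was −0.022 with 7 of 17 higher (0.528).

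Immediate early genes, chosen after the values were seen, included the largest differences of the list in the mean of both methamphetamine groups against controls. Dusp1, a MAP kinase phosphatase, differed by −0.62 ± 0.33 (SE), Fos by −0.60 ± 0.28, Arc, a regulator of synaptic receptors, by −0.55 ± 0.26 and Egr2 by −0.52 ± 0.22. None passed over all genes (limma adjusted p = 0.55, 0.505, 0.509 and 0.443) or adjusted over the list alone (0.261 each). Npas4, an activity-dependent factor of the same list, differed by 0.039 ± 0.27.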
